A study of Mus musculus with 20 samples.

How the data were processed

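RNA was measured by sequencing in 20 libraries, 4 each from lung cells cultured in 4 orders of 2D plates and 3D collagen hydrogels and from sorted uncultured lung cells, all of male C57BL/6 mice. Libraries were grouped by the culture condition in their labels. The replicate numbers in the labels were used only as names, since libraries with the same number were no more alike than others. Per the submitters' processing notes, reads were aligned with HISAT and Bowtie2 to GRCm38.p6; the versions of these tools and the name of the counting program are not given in the sources used here. The authors deposited expected counts (expected_counts) per gene, made from these alignments, and 5.98% of the values are not whole numbers (tolerance 1e-06). The table has 67228 genes, of which 18012 carry values; 49216 are blank, 33250 of these without a symbol, and were left out. The 5 columns of group averages in the same table were not used here. Values were rounded to whole counts for the tests.

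Gene symbols are those of the deposited table, so that Ctgf, Cyr61, Wisp2 and Mkl1 stand for Ccn2, Ccn1, Ccn5 and Mrtfa. Of the genes with values 17888 matched the reference annotation of the same build, 17701 as protein coding, and 348 symbols differed from it; coordinates are those of that annotation, counted from 1. The cultured libraries held 19.67 to 20.33 M counts and the sorted ones 11.66 to 13.95 M, with 14487 to 15444 and 15951 to 16294 genes detected. No replicates held identical values, and the chi-square per degree of freedom between replicates ran from 2.94 to 43.38.

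Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, libraries scaled with TMM, and quasi-likelihood F tests run for each contrast, with Benjamini-Hochberg adjustment and calls at an adjusted p below 0.05. Contrasts between cultures used a fit of the 16 cultured libraries (13704 genes, common biological coefficient of variation 0.122), and contrasts with sorted cells a fit of all 20 (14715 genes, 0.112). Levels are TMM-scaled CPM on the 20-library scaling. The interaction is the 3D-3D minus 3D-2D effect less the 2D-3D minus 2D-2D effect. For genes with 0 counts in a group the fitted fold is not given, and a bound with a floor of 3 counts over the group takes its place. Where Aqp4, Ccl21a, Hsd3b6 and Ltf had counts in only 1 library of a group, levels are given instead.

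Gene lists (19 by function, 18 by cell type; 595 of 612 genes matched, 15 in more than 1 list) were written before the files were opened and tested with camera at a preset correlation of 0.01, for lists with at least 3 tested genes, with adjustment over the lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. The list of mitochondrially encoded genes had no gene with values and is not analysed here, and red blood cell markers were tested only against sorted cells. For the position, genes were called between 2 libraries of 2D-2D and 2 of 3D-3D. The mean of the higher genes less that of the lower ones was scaled to 0 and 1 on the other libraries of those groups and averaged over all such choices. The distance was the root mean square of log2 differences from the sorted mean (prior count 2). Both were compared between groups with two-sided exact permutation tests, whose smallest p is 0.0286 for 4 against 4 libraries and 0.0571 for 3 against 4.

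The samples, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 5 higher and 5 lower genes with the largest change among called genes with at least 10 CPM in a group and no overlap of replicates, up to 3 higher and 3 lower members of each functional list, the 2 most abundant members of each cell type list, and 20 genes named in advance; the interaction used only the largest changes and the genes named in advance. It gave 1388 pairs of gene and comparison, of which the text names 273 in rank order, apart from some results that are not reported here.

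Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, other filters, a block for the replicate number, a minimum change of 2-fold, other sets of libraries in the fit and each library left out in turn. Scaling by library size alone was added after the data had been seen. On counts simulated with known changes, the test of 3D-3D against 2D-2D recovered 22%, 62%, 98% and 100% of genes changed by 1.25, 1.5, 2 and 4 times (50 genes each) with 5 false calls, the interaction 8%, 36%, 86% and 98% with 6, and 2D-2D against sorted 20%, 72%, 88% and 96% with 2. Only these genes changed there, as many up as down. The scaling was therefore not tested for comparisons in which most genes differ. Positions made at 0.75 and 0.25 came back as 0.74 and 0.234. Genes of close families (Hba, Sprr2, Hspa1, Hsd3b) share sequence, and their counts are uncertain.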

Results

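Lung tissue of male C57BL/6 mice was digested with collagenase, and the cells were cultured for 4 days either on flat plastic (2D) or inside a collagen hydrogel (3D). They were then passaged and cultured for 2 more days on the same or on the other substrate, which gave 4 groups named by the first and the second culture: 2D-2D, 2D-3D, 3D-2D and 3D-3D. A further group, called sorted here, held uncultured lung cells depleted with beads of leukocytes (CD45), epithelial cells (EpCAM) and endothelial cells (CD31). It still held the highest shares of counts of all groups for endothelial (0.514%), airway (0.204%), alveolar type 2 (0.12%), lymphocyte (0.0761%) and neutrophil markers (0.0713%). Each of the 5 groups had 4 RNA-seq libraries. The cultures started from unsorted digests, so that cells other than fibroblasts could be carried into them. The design asks how far the expression state set by the first substrate persists after the move to the other. RNA of whole cultures cannot tell such a state from a different mix of cells left by the first culture. This holds for the positions and distances below as well.

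The cultured libraries held between 19.67 and 20.33 M counts and the sorted libraries between 11.66 and 13.95 M. In principal components of the 16 cultured libraries, the first component (61.6% of the variance) parted the libraries by the second culture and the next (18.7%) by the first culture. Replicate 3 of 3D-3D stood apart from the other 3D-3D libraries, with a chi-square per degree of freedom between 35.98 and 43.38 in its pairs and at most 28.11 in all other pairs of replicates, where counting noise alone gives 1. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Gene changes are given as log2 fold change ± SE with n = 4 libraries per group, and levels as CPM (counts scaled to library size and TMM factor) ± SD. The SE is approximate, being the fitted change without shrinkage divided by the square root of the F statistic. It is unreliable for genes with few counts in a group.

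The first comparison asked how cells kept on 3D throughout differed from cells kept on 2D throughout. The contractile genes, whose products build the stress fibres of myofibroblasts and smooth muscle, fell in 3D-3D: all 16 tested members were lower. Acta2, the smooth muscle actin that marks myofibroblasts (gene 11475, chromosome 19, 34240336 to 34255585 in GRCm38.p6), stood at 549 ± 208 CPM in 3D-3D and 14300 ± 803 CPM in 2D-2D, a log2 fold change of -4.71 ± 0.20 (SE). Cnn1 (calponin, -6.64 ± 0.22), Lmod1 (an actin nucleator of smooth muscle, -6.03 ± 0.17) and Tagln (transgelin, an actin-binding protein, -3.57 ± 0.15) moved the same way. Of the 20 genes of the actin cytoskeleton and focal adhesions, 19 fell, among them Zyx, the adhesion protein zyxin (-2.90 ± 0.10). The contractile list was lower than other genes at adjusted p = 1.51e-09 by camera and at adjusted p = 0.133 with an estimated correlation, and the cytoskeletal list at 8.8e-09 and at adjusted p = 0.0486 with an estimated correlation. In all 4 of the 3D-3D libraries the mean level of either list lay below all 2D-2D libraries.

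Most targets of YAP and TAZ and most mechanosensor and mechanotransduction genes were lower as well. These data hold no measure of mechanical load. Of 22 targets of YAP and TAZ, the coactivators that enter the nucleus on stiff substrates, 15 fell and 5 rose (adjusted p = 0.00202, and adjusted p = 0.228 with an estimated correlation). Amotl2 (-4.21 ± 0.22), Ankrd1 (-3.97 ± 0.19) and Ctgf, a matricellular protein (-2.97 ± 0.12), fell, while Igfbp3, a carrier of insulin-like growth factors, rose (2.65 ± 0.22). Among 21 mechanosensor and mechanotransduction genes 17 fell and 2 rose (adjusted p = 2.26e-05, and adjusted p = 0.0526 with an estimated correlation). Those that fell included Mkl1, an actin-regulated coactivator of serum response factor (-2.36 ± 0.10), Tead1, the DNA-binding partner of YAP (-2.33 ± 0.15), the stretch-gated channel Piezo1 (-2.26 ± 0.13) and Yap1 itself (-0.72 ± 0.08).

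Matrix genes moved both ways. Of 26 collagens and structural matrix genes 17 fell and 8 rose (adjusted p = 0.0323, and adjusted p = 0.531 with an estimated correlation). The fibrillar collagen gene Col11a1 (-5.44 ± 0.21), Col8a1 (-4.99 ± 0.23) and Col1a1, the main chain of type I collagen (-2.06 ± 0.12), fell, whereas Dcn (decorin, a collagen-binding proteoglycan, 4.21 ± 0.12), Eln (elastin, 3.79 ± 0.21) and Col3a1 (1.08 ± 0.13) rose. Basement membrane genes fell in 11 of 12 cases (adjusted p = 1.45e-05, and adjusted p = 0.228 with an estimated correlation), with Nid2, a laminin-binding linker, at -4.02 ± 0.21. Of 15 genes of collagen crosslinking and maturation 9 fell and 1 rose (adjusted p = 0.00711, and adjusted p = 0.38 with an estimated correlation). Matrix proteases and their inhibitors were not called as a list (adjusted p = 0.287): 12 rose and 9 fell of 24, with Serpine2 (a protease inhibitor, 3.33 ± 0.12) and Mmp2 (a gelatinase, 2.85 ± 0.11) among those higher.

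Inflammatory cytokines and chemokines rose in 23 of 32 cases and fell in 6 (adjusted p = 0.000272, and adjusted p = 0.132 with an estimated correlation). Il1b, the fever cytokine interleukin-1 beta (gene 16176, chromosome 2, 129364569 to 129371164), went from 1.39 ± 0.24 CPM in 2D-2D to 126 ± 26.9 CPM in 3D-3D (6.48 ± 0.19), and Csf2, a growth factor of granulocytes and macrophages, rose by 5.77 ± 0.52. Csf1, the survival factor of macrophages, fell (-2.72 ± 0.09), and Il6 did not pass the test (0.19 ± 0.24, adjusted p = 0.465). Interferon response genes fell in 12 of 18 cases and rose in 2 (adjusted p = 0.021, and adjusted p = 0.372 with an estimated correlation), with the ubiquitin-like Isg15 at -2.60 ± 0.16. Scaled by library size alone, 6 fell and 3 rose. All 26 cell cycle genes fell (adjusted p = 1.07e-08, and adjusted p = 0.27 with an estimated correlation), among them the mitotic kinase Plk1 (-2.69 ± 0.10), and the proliferation antigen Mki67 was lower (-1.15 ± 0.19). The lists of integrins and collagen receptors, TGF-beta response, p53 and senescence, hypoxia and glycolysis, cholesterol synthesis, lipid storage, unfolded protein stress, and immediate early and heat shock genes were not called, with adjusted p between 0.0788 and 0.95.

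Markers of other cells differed between the same groups. Of 16 airway, 14 lymphocyte and 9 neutrophil markers with values, only 10, 7 and 6 passed the filter on counts. A marker near 0 in 2D-2D passes only through counts in another culture. Numbers of such markers higher or lower between cultures, here and below, were therefore partly set by the filter. The shares of counts use all markers. Airway epithelial markers rose in 10 of 10 cases (adjusted p = 5.72e-05, and adjusted p = 0.132 with an estimated correlation) and took 0.0338 ± 0.0121% of counts in 3D-3D against 0.00142 ± 0.000143% in 2D-2D. Krt15 and Krt6a, keratins of basal epithelium, and the water channel Aqp4 were at 0 in 2D-2D and at least 540-fold, 519-fold and 361-fold higher in 3D-3D (floor of 3 counts over the group). These bounds use counts summed over 3D-3D, whose libraries varied widely (23.3 ± 20.4, 22.3 ± 16.7 and 15.6 ± 15.8 CPM). Krt8, a keratin of simple epithelia, rose by 4.95 ± 0.32. Endothelial markers rose in 16 of 18 cases (adjusted p = 3.02e-06, and adjusted p = 0.0486 with an estimated correlation), with Ace, the angiotensin-converting enzyme, at 5.49 ± 0.17. Macrophage markers rose in 19 of 22 (adjusted p = 1.66e-05, and adjusted p = 0.243 with an estimated correlation) and made up 1.83 ± 0.173% against 0.956 ± 0.0836% of counts, although Lyz2 (lysozyme) rose by only 0.49 ± 0.12 with overlapping libraries. Neutrophil markers rose in 6 of 6 (adjusted p = 0.0133, and adjusted p = 0.228 with an estimated correlation). Lymphocyte markers rose in 7 of 7 (adjusted p = 0.000609, and adjusted p = 0.0486 with an estimated correlation) and alveolar type 2 markers in 7 of 10 (adjusted p = 0.0443, and adjusted p = 0.283 with an estimated correlation). Alveolar fibroblast markers rose in 10 of 16 and fell in 5, and adventitial fibroblast markers rose in 9 of 16 and fell in 7, with neither list called (adjusted p = 0.0854 and 0.394). The fibroblast receptor Pdgfra rose by 1.14 ± 0.10. The mast cell and basophil list was not called (adjusted p = 0.819), with the basophil protease Mcpt8 lower (-5.90 ± 0.24). Nor were peribronchial myofibroblast (5 of 9 higher, 1 lower, adjusted p = 0.116), pericyte (7 of 11 higher, 1 lower, 0.0788), mesothelial (5 of 12 higher, 3 lower, 0.803). The same held for alveolar type 1 (8 of 11 higher, 3 lower, 0.156), Schwann and nerve (3 of 4 higher, 0.156), cartilage and bone (2 of 4 higher, 1 lower, 0.62) and cardiac and skeletal muscle markers (2 of 5 higher, 1 lower, 0.819).

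In all, 10078 of 13704 genes tested differed between 3D-3D and 2D-2D (5294 higher, 4784 lower), 3944 of them by at least 2-fold, in edgeR's quasi-likelihood test. The strongest falls included Hsd3b6 and Hsd3b1, enzymes of steroid synthesis, the matricellular gene Wisp2 (-7.26 ± 0.31) and the adrenergic receptor Adra1d (-6.91 ± 0.39). Hsd3b1 was at 0 in 3D-3D and at least 295-fold lower. Hsd3b6 stood at 74.4 ± 1.43 CPM in 2D-2D and at 0.0115 ± 0.023 CPM in 3D-3D, where 1 library held its counts. The Hsd3b genes resemble each other closely, and their values are uncertain. Adjusted over the list alone, the counts of the lists given for this comparison were the same, except 13 higher instead of 12 for the proteases. Scaled by library size alone, the median of all genes moved by 0.32 on the log2 scale and 7289 genes were higher and 2996 lower.

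**Figure D1:**
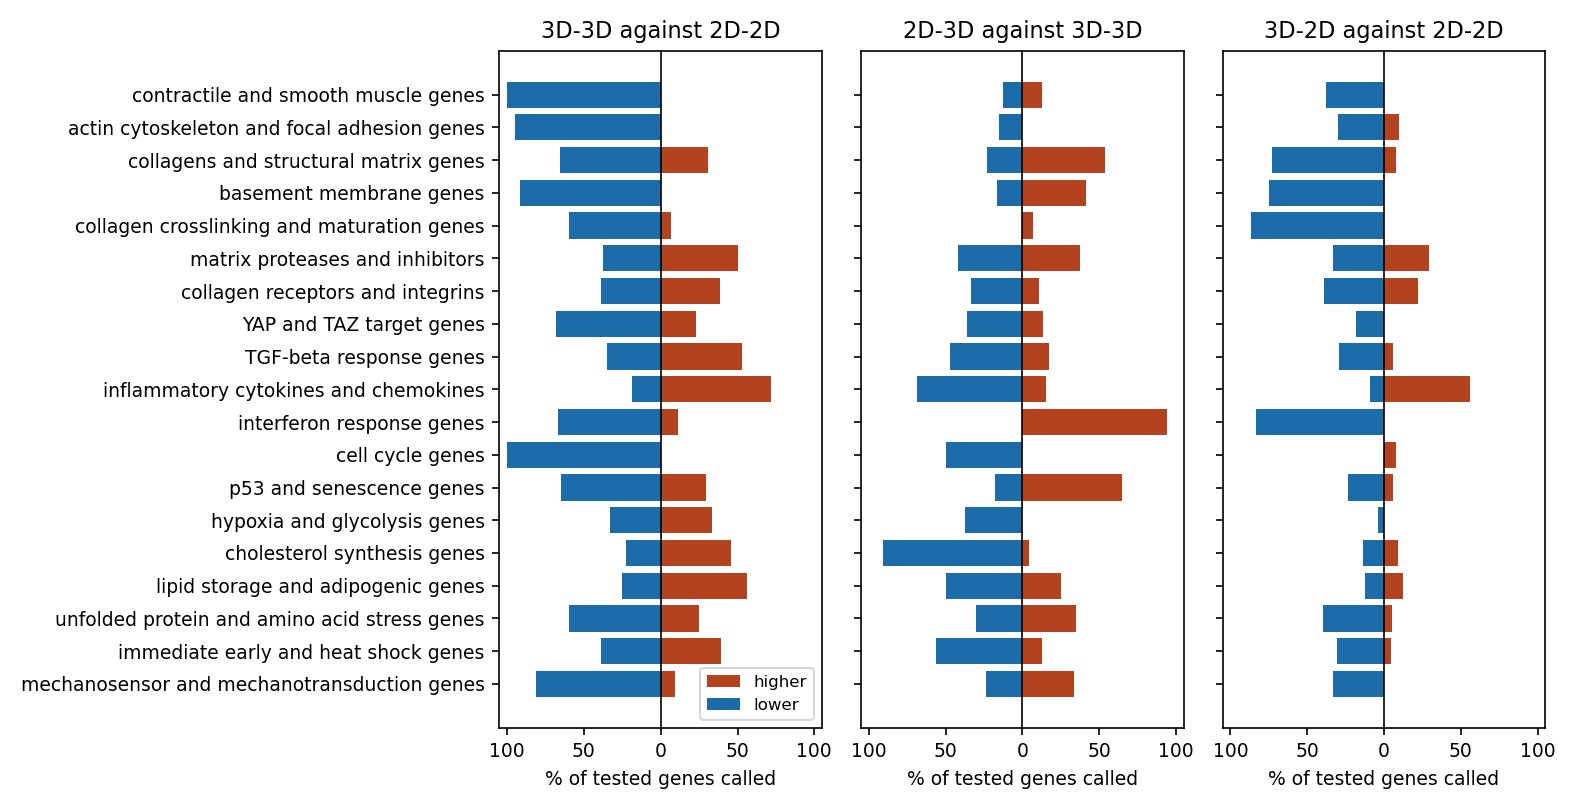
Percentage of the tested genes of each functional list that were called higher (right, red) or lower (left, blue) in 3 comparisons, with 4 libraries per group. All 16 contractile genes were lower in 3D-3D than in 2D-2D, and 17 of 18 interferon response genes were higher in 2D-3D than in 3D-3D.

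Cells moved from 2D to 3D held less RNA of the contractile genes at the end of the second culture than cells kept on 2D. No library was taken at the move. Falls and rises are therefore differences between cultures at the same end point, not changes measured over time. In 2D-3D all 16 fell relative to 2D-2D, among them Acta2 to 722 ± 131 CPM (-4.31 ± 0.20), Cnn1 (-5.63 ± 0.21) and Tagln (-3.40 ± 0.15). The list was lower at adjusted p = 6.04e-10 (adjusted p = 0.303 with an estimated correlation). Acta1, the skeletal actin, which is not in this list, was also lower (-5.96 ± 0.49). The cytoskeletal and focal adhesion genes fell in 19 of 20 cases, Zyx among them (-2.70 ± 0.10), at adjusted p = 1.67e-09 (adjusted p = 0.0797 with an estimated correlation). YAP and TAZ targets fell in 15 of 22 and rose in 5 (adjusted p = 0.0011, and adjusted p = 0.333 with an estimated correlation), with Ankrd1 (-5.42 ± 0.21), Amotl2 (-3.74 ± 0.21) and Ctgf (-3.53 ± 0.12). Mechanosensor genes fell in 17 of 21 and rose in 1 (adjusted p = 2.66e-05, and adjusted p = 0.105 with an estimated correlation), Tead4 by -3.83 ± 0.32 on the log2 scale. All 26 cell cycle genes fell (adjusted p = 4.57e-10, and adjusted p = 0.333 with an estimated correlation), including Plk1 (-2.94 ± 0.10).

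The basement membrane genes fell in 12 of 12 cases in 2D-3D (adjusted p = 2.66e-05, and adjusted p = 0.333 with an estimated correlation), with the integrin ligand Npnt at -3.04 ± 0.13. Collagen crosslinking genes fell in 10 of 15 and rose in 3 (adjusted p = 0.021, and adjusted p = 0.693 with an estimated correlation). Collagens and structural genes were not called as a list (adjusted p = 0.28): 15 fell, such as Col8a1 (-3.81 ± 0.21) and Col1a1 (-0.93 ± 0.12), and 10 rose, such as Eln (3.37 ± 0.20), Postn (periostin, a matricellular protein, 3.04 ± 0.16) and Col3a1 (1.43 ± 0.13). Proteases and their inhibitors were not called as a list: 13 rose, such as Mmp2 (3.52 ± 0.11) and the collagen-degrading cathepsin Ctsk (2.58 ± 0.12), and 9 fell. Cytokines rose in 16 of 32 and fell in 12 (adjusted p = 0.436): Il1b (4.76 ± 0.19) and the monocyte chemokine Ccl8 (4.56 ± 0.28) rose, and Csf1 (-2.97 ± 0.09) and Il6 (-1.0 ± 0.24) fell. Macrophage markers rose in 20 of 22 cases (adjusted p = 4.19e-08, and adjusted p = 0.333 with an estimated correlation) and from 0.956 ± 0.0836% to 2.76 ± 0.213% of counts, with Lyz2 at 1.34 ± 0.13. Endothelial markers rose in 12 of 18 and fell in 1 (adjusted p = 0.0103, and adjusted p = 0.333 with an estimated correlation), led by Ace (5.89 ± 0.17). Airway markers were not called as a list (adjusted p = 0.448), and Krt8 did not pass the test (-0.15 ± 0.38, adjusted p = 0.739).

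Between 2D-3D and 2D-2D 9763 genes differed (5005 higher, 4758 lower), 3799 by at least 2-fold. The tight junction gene Cldn2 was at 0 in 2D-2D and at least 294-fold higher in 2D-3D. Chl1, a neural adhesion molecule (7.78 ± 0.33), and Agt, angiotensinogen (6.99 ± 0.34), were also among those that rose most. The granzyme Gzme (-6.78 ± 0.30), Hsd3b6 (-6.66 ± 0.24) and Mcpt8 (-6.39 ± 0.26) fell most. Adjusted over the list alone, the counts of these lists were the same, except 21 instead of 20 for macrophages. Scaled by library size alone, the median moved by 0.279 and 6708 genes were higher and 3224 lower.

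Cells moved from 3D to 2D held more RNA of the contractile genes than cells kept in 3D. All 16 rose in 3D-2D relative to 3D-3D: Acta2 reached 10500 ± 450 CPM (4.26 ± 0.20), with Cnn1 at 5.83 ± 0.22 and Tagln at 3.28 ± 0.15 (list adjusted p = 2.17e-10; adjusted p = 0.137 with an estimated correlation). All 20 cytoskeletal genes rose, Zyx by 2.44 ± 0.10 (adjusted p = 2.26e-10, and adjusted p = 0.0525 with an estimated correlation). YAP and TAZ targets rose in 15 of 22 and fell in 5 (adjusted p = 0.00349, and adjusted p = 0.28 with an estimated correlation): Ankrd1 (4.17 ± 0.19) and Amotl2 (3.75 ± 0.21) rose and Igfbp3 fell (-3.06 ± 0.22). Mechanosensor genes rose in 17 of 21 and fell in 1 (adjusted p = 6.16e-05, and adjusted p = 0.0636 with an estimated correlation), with Mkl1 at 2.06 ± 0.10 and Piezo1 at 1.96 ± 0.13. All 26 cell cycle genes rose (adjusted p = 2.26e-10, and adjusted p = 0.28 with an estimated correlation), including Plk1 (2.62 ± 0.10), and Mki67 rose by 0.73 ± 0.18.

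Basement membrane genes rose in 11 of 12 cases on the move from 3D to 2D (adjusted p = 0.000234, and adjusted p = 0.316 with an estimated correlation), with Nid2 at 3.50 ± 0.21. Collagens and structural genes rose in 13 of 26 and fell in 9 and were not called (adjusted p = 0.54, with a median of 0.22 and a mean of -0.04). Col11a1 (3.98 ± 0.21) and Col1a1 (0.94 ± 0.12) rose, and Eln (-4.42 ± 0.22), Dcn (-3.64 ± 0.11) and Col3a1 (-1.73 ± 0.13) fell. Cytokines fell in 19 of 32 and rose in 8 (adjusted p = 0.0491, and adjusted p = 0.336 with an estimated correlation). Il1b (-4.07 ± 0.16) and the epithelial chemokine Cxcl15 (-5.53 ± 0.64) fell and Csf1 rose (2.30 ± 0.09). Il6 rose by 0.58 ± 0.23 with overlapping libraries (adjusted p = 0.0338). That call was lost without 3D-2D replicate 1 (0.30, adjusted p = 0.172), 3D-3D replicate 3 (0.37, 0.109) or 3D-3D replicate 4 (0.58, 0.0557). It was also lost in DESeq2 (adjusted p = 0.0647), with only these groups in the fit (0.0559) and scaled by library size alone (0.35, 0.213). Psat1, an enzyme of serine synthesis, rose by 2.83 ± 0.12. Peribronchial and ductal myofibroblast markers fell in 7 of 9 (adjusted p = 0.0367, and adjusted p = 0.241 with an estimated correlation) and pericyte markers in 8 of 11 (adjusted p = 0.0367, and adjusted p = 0.137 with an estimated correlation), each with 1 higher. Lymphocyte markers fell in 7 of 7 (adjusted p = 0.00123, and adjusted p = 0.0525 with an estimated correlation). Endothelial markers fell in 16 of 18 (adjusted p = 4.15e-06, and adjusted p = 0.0525 with an estimated correlation, with Ace at -4.24 ± 0.15). Airway markers fell in 10 of 10 (adjusted p = 0.00209, and adjusted p = 0.241 with an estimated correlation, with Krt8 at -1.03 ± 0.25 and its libraries overlapping). Macrophage markers were not called (adjusted p = 0.387), and Lyz2 was at 0.03 ± 0.12 (adjusted p = 0.858).

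Between 3D-2D and 3D-3D 9662 genes differed (4494 higher, 5168 lower), 3357 by at least 2-fold. Mcpt8 (5.96 ± 0.24) and Wisp2 (5.56 ± 0.30) were among those that rose most. Among those that fell most were Aqp4, Chl1 (-7.76 ± 0.28) and Sprr2b, an envelope protein of squamous epithelium (-7.56 ± 0.42, uncertain because its family shares sequence). Aqp4 stood at 0.0264 ± 0.0529 CPM in 3D-2D, where 1 library held its counts, and at 15.6 ± 15.8 CPM in 3D-3D. Adjusted over the list alone, the counts of these lists were the same, except that 1 basement membrane gene was then lower. Scaled by library size alone, the median moved by -0.229 and 3079 genes were higher and 6774 lower.

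**Figure D2:**
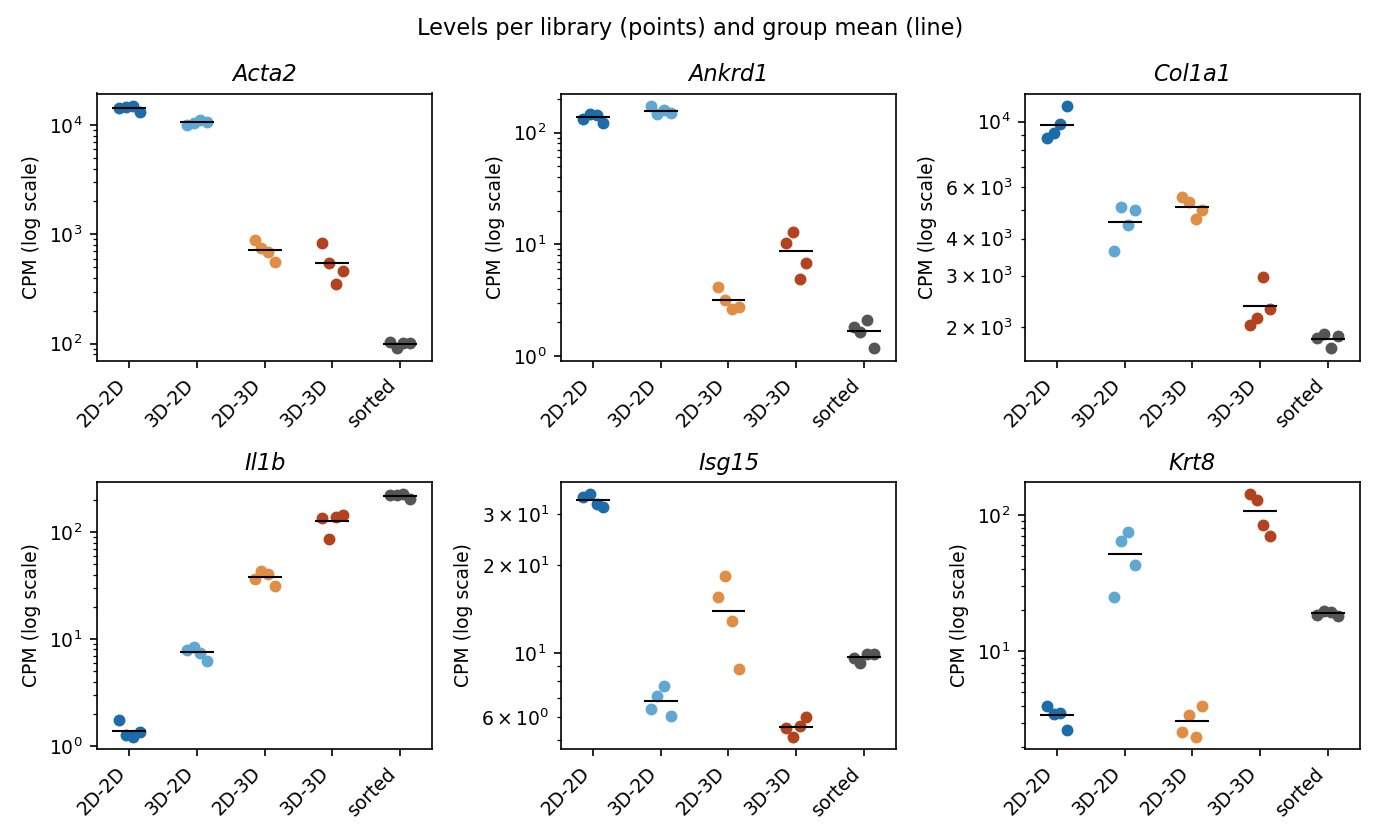
Levels of 6 genes in CPM (log scale) in the 20 libraries, by group, with a line at each group mean. Acta2 stood at 14300 CPM in 2D-2D, 10500 in 3D-2D, 722 in 2D-3D and 549 in 3D-3D, and Krt8 at 107 CPM in 3D-3D and 3.08 in 2D-3D.

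To place the moved cells between the unmoved ones, each library was scored over the genes that differed between 2D-2D and 3D-3D, chosen on some of those libraries and scored on the others, with 0 at the 2D-2D mean and 1 at the 3D-3D mean. Between 6630 and 9612 genes entered. The 2D-3D cultures lay at 0.793 ± 0.013 (SD, n = 4) and the 3D-2D cultures at 0.19 ± 0.039. These are 79.3% and 81% of the distance from the unmoved cultures of their first substrate to those of their second. How far the cells had come from their state at the move was not measured. Either group differed from both ends in all 4 libraries (two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 allows). As a median over genes, the values were 0.947 and 0.143.

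**Figure D3:**
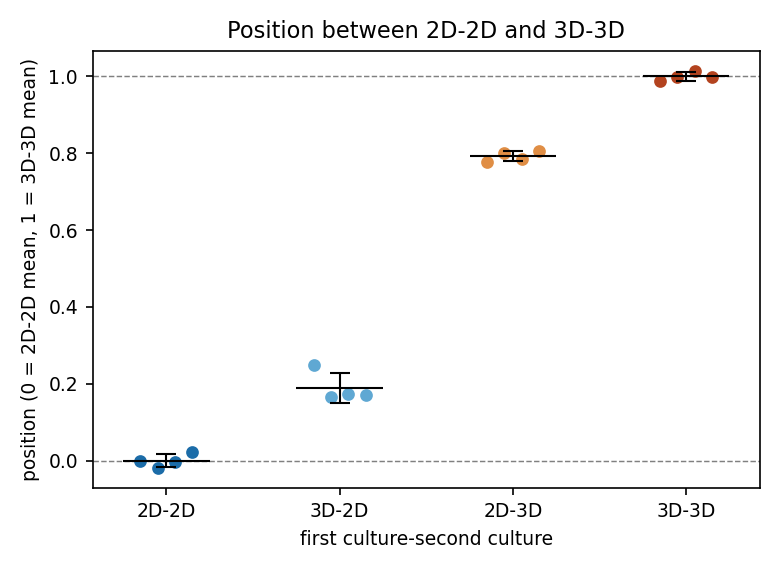
Position of each cultured library (point) between the 2D-2D mean (0) and the 3D-3D mean (1), with group mean and SD (line and bar, n = 4). The 2D-3D libraries centre on 0.793 and the 3D-2D libraries on 0.19.

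The difference between 2D-3D and 2D-2D was compared with that between 3D-3D and 3D-2D, 2 contrasts with no library in common. Across 13704 genes, which are not independent replicates, the effects of the second culture correlated with Pearson's r = 0.772 and Spearman's rho = 0.816. Of these, 3935 genes were higher in both and 3799 lower in both, where independent lists would share 1887.5 and 1560.3, and 256 went opposite ways. The effects of the first culture, seen after 2D and after 3D, correlated with r = 0.572 and rho = 0.21. Here 496 genes were higher in both (199.9 if independent), 440 lower in both (185.2) and 418 opposite. Of the genes called in both contrasts 69.1% went the same way, against 96.8% for the second culture. How many opposite genes independent lists would give was not computed. The excess of first-culture genes called in both contrasts therefore does not by itself show a shared direction. Over the 9153 genes with a mean of at least 10 CPM the first-culture values were r = 0.453 and rho = 0.113. There 62% of the genes called in both went the same way. For the second culture the values were r = 0.88, rho = 0.874 and 96.7%.

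Among cells now in 3D, those that had begun on 2D were compared with those that had always been in 3D, which asks what of the first culture remained. What remained can be a kept state or a different mix of surviving cells. Neither this comparison nor the one on 2D can tell these apart. Of the contractile genes 2 of 16 were higher and 2 lower, each between 2 and 4 with 1 library left out, and the list was not called (adjusted p = 0.689). Acta2 was at 0.41 ± 0.17 (adjusted p = 0.0932) and Tagln at 0.17 ± 0.14 (adjusted p = 0.396). The Acta2 difference passed without 2D-3D replicate 4 (0.51, adjusted p = 0.0421) or 3D-3D replicate 1 (0.68, adjusted p = 0.00069), by limma-voom (0.46, adjusted p = 0.0485) and with a block for the replicate number (0.43, adjusted p = 0.0483). YAP and TAZ targets were not called as a list (adjusted p = 0.245), with 8 of 22 lower, such as Igfbp3 (-1.67 ± 0.20) and Ankrd1 (-1.45 ± 0.22), and 3 higher (3 to 5 with 1 library left out). Collagens and structural genes were higher in 14 of 26 cases and lower in 6 (adjusted p = 0.00999, and adjusted p = 0.474 with an estimated correlation). In 3 of 4 libraries the list lay above all 3D-3D libraries. Col11a1 (2.43 ± 0.23), Postn (1.68 ± 0.15) and Col1a1 (1.13 ± 0.12) were higher and Dcn lower (-1.35 ± 0.10).

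Inflammatory and interferon genes went opposite ways in this comparison. Cytokines and chemokines were lower in 22 of 32 cases in 2D-3D and higher in 5 (adjusted p = 6.59e-10, and adjusted p = 0.0207 with an estimated correlation): Il11 (-3.97 ± 0.19), the iron-sequestering lipocalin Lcn2 (-3.95 ± 0.13) and Csf2 (-3.67 ± 0.40) were lower and Ccl8 higher (2.70 ± 0.23). Interferon response genes were higher in 17 of 18 (adjusted p = 6.59e-10, and adjusted p = 0.0367 with an estimated correlation), with Ifit3 at 1.95 ± 0.25 and the antiviral Rsad2 at 1.61 ± 0.30. Cholesterol synthesis genes were lower in 20 of 22 (adjusted p = 6.59e-10, and adjusted p = 0.0594 with an estimated correlation), with Idi1, an isomerase of that pathway, at -1.18 ± 0.15, and the only higher member was Dhcr7 (0.40 ± 0.08). Genes of the p53 and senescence list were higher in 11 of 17 and lower in 3 (adjusted p = 0.00549, and adjusted p = 0.0367 with an estimated correlation), such as the p53 target Zmat3 (0.97 ± 0.10) against the desmosomal Perp (-1.75 ± 0.26). Hypoxia and glycolysis genes were lower in 9 of 24 (adjusted p = 0.000584, and adjusted p = 0.474 with an estimated correlation), including the oxygen sensor Egln3 (-1.68 ± 0.32) and, with overlapping libraries, Ndrg1 (-1.32 ± 0.28); 3D-3D replicate 3 held the highest Egln3 level. The mean log2 CPM of this list was 8.769 in that library against 7.796 to 8.065 in the other 3D-3D libraries, and in 3 of 4 libraries of 2D-3D it lay below all of 3D-3D. Without 2D-3D replicate 1, 15 were lower, and without 3D-3D replicate 2, 16. Over all libraries left out, the number lower ran from 7 to 16. Cell cycle genes were lower in 13 of 26 (adjusted p = 0.000233, and adjusted p = 0.474 with an estimated correlation), although in only 1 of 4 libraries did their mean lie below all 3D-3D libraries. Without 2D-3D replicate 4 or without 3D-3D replicate 1, 8 were lower, and over all libraries left out between 8 and 19. Bub1 (-0.54 ± 0.16, adjusted p = 0.0132) lost its call without 2D-3D replicate 4 (-0.45, adjusted p = 0.0526), Cdk1 (-0.50 ± 0.15, adjusted p = 0.0149, libraries overlapping) without that library (-0.37, 0.0615) or 3D-3D replicate 1 (-0.34, 0.0821), and Mki67 was not called (-0.19 ± 0.19, adjusted p = 0.498). Collagen receptors and integrins were lower in 6 of 18 and higher in 2 (adjusted p = 0.0239, and adjusted p = 0.396 with an estimated correlation; Itga3, a laminin-binding integrin also found on epithelia, -4.35 ± 0.23). TGF-beta response genes were lower in 8 of 17 and higher in 3 (adjusted p = 0.0146, and adjusted p = 0.079 with an estimated correlation). Immediate early and heat shock genes were lower in 13 of 23 and higher in 3 (adjusted p = 0.0182, and adjusted p = 0.474 with an estimated correlation). In 3 of 4 libraries of 2D-3D their mean log2 CPM lay below all of 3D-3D. It was 6.597 and 6.564 in 3D-3D replicate 1 and 3D-3D replicate 2, and 5.961 and 5.939 in 3D-3D replicate 3 and 3D-3D replicate 4, among the 2D-3D values of 5.82 to 6.008.

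Cell type markers differed as well. Airway epithelial markers were lower in 2D-3D in 8 of 10 cases (adjusted p = 6.59e-10, and adjusted p = 0.0209 with an estimated correlation), at 0.00211 ± 7.84e-05% of counts against 0.0338 ± 0.0121% in 3D-3D. Krt6a and Aqp4 were at 0 in 2D-3D and at least 631-fold and 440-fold lower, and Krt8 fell by 5.10 ± 0.32. Lactoferrin (Ltf) stood at 0.0238 ± 0.0476 CPM in 2D-3D, where 1 library held its counts, and at 74.4 ± 58.4 CPM in 3D-3D. Endothelial markers were lower in 13 of 18 and higher in 1 (adjusted p = 7.47e-09, and adjusted p = 0.0207 with an estimated correlation). Lymphocyte markers were lower in 5 of 7 and higher in 1 (adjusted p = 0.00125, and adjusted p = 0.0367 with an estimated correlation, with the B cell receptor chain Cd79a at -6.69 ± 0.36). Neutrophil markers were lower in 5 of 6 (adjusted p = 0.00189, and adjusted p = 0.101 with an estimated correlation). Alveolar type 2 markers were lower in 6 of 10 (adjusted p = 0.00176, and adjusted p = 0.101 with an estimated correlation), and alveolar type 1 markers in 6 of 11 with 1 higher (adjusted p = 0.0132, and adjusted p = 0.0594 with an estimated correlation). The water channel Aqp1 was lower (-1.30 ± 0.11). Among stromal lists, alveolar fibroblast markers were lower (8 of 16 lower, 2 higher, adjusted p = 0.0202; adjusted p = 0.316 with an estimated correlation). So were peribronchial myofibroblast (6 of 9 lower, adjusted p = 0.00175; adjusted p = 0.0594 with an estimated correlation) and pericyte markers (6 of 11 lower, 2 higher, adjusted p = 0.0146; adjusted p = 0.0624 with an estimated correlation). Macrophage markers were higher in 12 of 22 and lower in 2 (adjusted p = 0.00156, and adjusted p = 0.396 with an estimated correlation), at 2.76 ± 0.213% of counts against 1.83 ± 0.173%, with Lyz2 at 0.85 ± 0.12. In only 1 of 4 libraries did their mean lie above all 3D-3D libraries.

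In all, 3793 genes differed between 2D-3D and 3D-3D (1741 higher, 2052 lower), 1179 of them by at least 2-fold; Wisp2 (4.64 ± 0.30), the calcium-binding S100a4 (2.99 ± 0.16) and the lymphatic growth factor Vegfd (2.83 ± 0.28) led the higher ones. With library size alone as the scaling, 1386 were higher and 2284 lower. Adjusted over the list alone, 20 cell cycle, 12 hypoxia, 9 TGF-beta and 9 YAP and TAZ genes were lower, the last with 5 higher, and 15 collagens were higher and 8 lower. By that count 3 contractile genes were higher and 3 lower, 12 p53 genes were higher, and macrophage markers were higher in 13 cases and lower in 4, endothelial ones higher in 2 and lower in 15. Alveolar fibroblast markers were then higher in 4 cases, and 7 peribronchial, 7 pericyte and 7 alveolar type 2 markers were lower, with the other counts of this comparison the same.

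Among cells now on 2D, those that had begun in 3D were compared with those always on 2D. Matrix genes were lower: 19 of 26 collagens and structural genes fell and 2 rose (adjusted p = 1.61e-10, and adjusted p = 0.13 with an estimated correlation). Fbln2, a matrix glycoprotein (-1.59 ± 0.10), Col11a1 (-1.46 ± 0.15) and Col1a1 (4550 ± 684 CPM against 9750 ± 1140 CPM, -1.11 ± 0.12) were lower. Lum, the proteoglycan lumican, was higher (1.26 ± 0.24). Crosslinking and maturation genes fell in 13 of 15 (adjusted p = 4.82e-09, and adjusted p = 0.13 with an estimated correlation), including the crosslinking oxidase Lox (-1.19 ± 0.20) and the collagen hydroxylase P4ha2 (-0.82 ± 0.18). Basement membrane genes fell in 9 of 12 (adjusted p = 1.53e-05, and adjusted p = 0.252 with an estimated correlation, with Col4a2 at -0.87 ± 0.11). Interferon response genes fell in 15 of 18 (adjusted p = 2.1e-12, and adjusted p = 0.0483 with an estimated correlation), with Ifit1 (-2.65 ± 0.22) and Isg15 (-2.30 ± 0.16). Cytokines rose in 18 of 32 and fell in 3 (adjusted p = 4.82e-09, and adjusted p = 0.0477 with an estimated correlation), with Csf2 (4.37 ± 0.57) and Il1b (2.41 ± 0.22) higher. The interferon-induced chemokine Cxcl10, of the cytokine list, was lower (-1.11 ± 0.35, adjusted p = 0.0288, libraries overlapping). That call was lost without 2D-2D replicate 4 (-0.56, adjusted p = 0.242), without 3D-2D replicate 1 (-0.93, 0.103), 3 (-1.04, 0.08) or 4 (-1.12, 0.0596) and by limma-voom (-0.96, 0.0549).

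Contractile genes fell in 6 of 16 cases in 3D-2D (adjusted p = 0.0069, and adjusted p = 0.531 with an estimated correlation), Cnn1 by -0.81 ± 0.17 on the log2 scale; scaled by library size alone, 2 fell and 1 rose. Without 3D-2D replicate 1, 3 fell. Acta2 (-0.45 ± 0.17, adjusted p = 0.0766) and Tagln (-0.29 ± 0.14, adjusted p = 0.147) were not called, but passed with only these groups in the fit (adjusted p = 0.000406 and 0.00749). Ankrd1 was at 0.19 ± 0.16 (adjusted p = 0.453), and the YAP and TAZ list was not called (adjusted p = 0.0835). Mechanosensor genes fell in 7 of 21 (adjusted p = 0.0151, and adjusted p = 0.228 with an estimated correlation; in 3 of 4 libraries below all 2D-2D libraries), with the caveolar protein Cav1 at -1.10 ± 0.15; scaled by library size alone, 2 fell. Between 3 and 6 fell with 1 library left out, being 3 without 2D-2D replicate 2 or 3D-2D replicate 1 and 4 without 2D-2D replicate 3, 2D-2D replicate 4 or 3D-2D replicate 3. Yap1 (-0.24 ± 0.08, adjusted p = 0.0427) lost its call without each of the 8 libraries in turn (adjusted p from 0.0591 to 0.137), with RLE size factors (0.0526), without a filter on low counts (0.0517) and scaled by library size alone (0.285). Mki67 was at -0.42 ± 0.18 (adjusted p = 0.116), and at -0.56 (adjusted p = 0.0301) without 2D-2D replicate 1. Hypoxia genes (1 of 24 lower, adjusted p = 0.0365; adjusted p = 0.605 with an estimated correlation) and immediate early and heat shock genes (7 of 23 lower, 1 higher, adjusted p = 0.0365; adjusted p = 0.587 with an estimated correlation) were called as lists. No hypoxia gene was called lower without each of the 8 libraries in turn, with RLE size factors or scaled by library size alone. Of the immediate early and heat shock genes 3 were lower scaled by library size alone, and between 3 and 6 with 1 library left out: 3 without 2D-2D replicate 2 or 3D-2D replicate 1, and 4 without 2D-2D replicate 1, 3D-2D replicate 3 or 3D-2D replicate 4.

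Airway markers were higher in 3D-2D in 6 of 10 cases (adjusted p = 8.4e-07, and adjusted p = 0.0729 with an estimated correlation), at 0.0098 ± 0.0033% of counts. Krt17 (7.99 ± 0.87), the epithelial junction gene Cldn4 (5.01 ± 0.41), Krt7 (4.11 ± 0.37), Krt8 (3.92 ± 0.31), Krt18 (3.17 ± 0.27) and the mesothelial antigen Msln (3.14 ± 0.32) rose, while Krt19 was at 0.26 ± 0.27 (adjusted p = 0.553). Of the 12 mesothelial markers 2 were higher and 3 lower, and the list was not called (adjusted p = 0.388). Macrophage markers rose in 20 of 22 and fell in 1 (adjusted p = 1.92e-16, and adjusted p = 0.0609 with an estimated correlation), to 1.52 ± 0.049% of counts, with Lyz2 at 0.52 ± 0.12. Neutrophil markers were higher as well (3 of 6, adjusted p = 0.0014; adjusted p = 0.13 with an estimated correlation). So were lymphocyte (5 of 7 higher, 1 lower, adjusted p = 0.0079; adjusted p = 0.0914 with an estimated correlation) and endothelial markers (4 of 18 higher, adjusted p = 0.00609; adjusted p = 0.191 with an estimated correlation). In all, 2793 genes differed (1335 higher, 1458 lower), 653 by at least 2-fold, with Hsd3b6 the most reduced of those named (-5.46 ± 0.22). Adjusted over the list alone, 21 collagens, 14 crosslinking, 11 basement membrane, 8 contractile and 8 mechanosensor genes were lower, 1 contractile gene, 22 cytokines and 8 airway markers higher, no hypoxia gene was called and 9 immediate early genes were lower. By that count 21 macrophage, 4 neutrophil and 6 endothelial markers were higher and 1 endothelial marker lower, with the other counts the same. Scaled by library size alone, 1887 genes were higher and 865 lower.

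The interaction tests whether the second substrate acted differently after a first culture in 3D than after one in 2D, as the 3D-minus-2D effect after 3D less that after 2D. It was called for 2654 genes (1407 above and 1247 below 0), 873 of them with a difference of at least 2-fold. With library size alone as the scaling, 1146 were above and 1416 below. Of the 16 contractile genes 2 were above 0 (2 to 5 with 1 library left out; adjusted p of the list 0.13). No difference was called for Acta2 (0.04 ± 0.25, adjusted p = 0.936), Tagln (0.12 ± 0.19, 0.737) or the collagen gene Col1a1 (-0.02 ± 0.16, 0.964). Ankrd1 lost less in 3D after a first culture in 3D (1.25 ± 0.28). The largest positive values were those of epithelial genes, Krt20 (9.44 ± 0.91), Krt19 (5.53 ± 0.43) and the Sprr2 genes Sprr2a1 and Sprr2a2 (6.24 ± 1.45 each, with identical counts; adjusted p = 0.00382, and 0.0796 by limma-voom) and Sprr2b (5.66 ± 0.90), which share sequence and are uncertain. Negative values were found for Ccl8 (-3.97 ± 0.39), the fractalkine receptor Cx3cr1 (-3.36 ± 0.27) and Wisp2 (-2.94 ± 0.38), and smaller ones for Tgfb1 (-0.48 ± 0.13) and the collagenase Mmp13 (-0.59 ± 0.16), against Timp1, an inhibitor of metalloproteases (0.78 ± 0.13). Macrophage markers had the lowest p of the lists (19 of 22 below 0 and 1 above, adjusted p = 1.48e-16; adjusted p = 0.135 with an estimated correlation). Calls near the threshold were those of Cldn2 (adjusted p = 0.0491), Hsd3b1 (0.0252), Ctgf (0.46 ± 0.16, 0.0463) and Yap1 (0.38 ± 0.12, 0.0228). Each was lost without some library, for example without 3D-2D replicate 3 for Cldn2 (adjusted p = 0.111), 3D-3D replicate 4 for Hsd3b1 (0.053) and Yap1 (0.056) and 3D-2D replicate 1 for Ctgf (0.12). By limma-voom the calls of Cldn2 (0.307), Hsd3b1 (0.0983) and Ctgf (0.0519) were lost, and with a block for the replicate number those of Cldn2 (0.0712) and Ctgf (0.06). The calls of Cldn2 (0.056), Ctgf (0.0676) and Yap1 (0.0808) were also lost when scaled by library size alone.

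Against the sorted, uncultured cells, 2D-2D showed the markers of resident fibroblasts lower and contractile, collagen crosslinking and cell cycle genes higher. Alveolar fibroblast markers fell in 17 of 17 cases (adjusted p = 3.01e-07, and adjusted p = 0.0302 with an estimated correlation): Inmt, a methyltransferase, from 3640 ± 234 CPM to 0.23 ± 0.165 CPM, Mfap4, a microfibril protein (-7.34 ± 0.23), the transcription factor Tcf21 (-2.35 ± 0.11) and Pdgfra (-1.53 ± 0.10). Adventitial fibroblast markers fell in 14 of 17 and rose in 3 (adjusted p = 0.00134, and adjusted p = 0.0729 with an estimated correlation). Contractile genes rose in 14 of 16 and fell in 2 (adjusted p = 1.43e-06, and adjusted p = 0.154 with an estimated correlation), with Cnn1 (9.16 ± 0.25), Actg2, the enteric smooth muscle actin (7.90 ± 0.24), and Acta2 (7.17 ± 0.21). Crosslinking genes rose in 14 of 15 (adjusted p = 0.000138, and adjusted p = 0.218 with an estimated correlation). Collagens and structural genes rose in 15 of 26 and fell in 10 and were not called (adjusted p = 0.29). Col11a1 (8.24 ± 0.32) and tenascin-C (Tnc, 6.29 ± 0.14) rose, Eln fell (-6.25 ± 0.21) and Col3a1 was at -0.08 ± 0.12 (adjusted p = 0.55), or -0.40 (adjusted p = 0.00423) scaled by library size alone. Cytoskeletal genes rose in 18 of 20 and fell in 1 (adjusted p = 3.62e-06, and adjusted p = 0.0661 with an estimated correlation). YAP and TAZ targets rose in 12 of 22 and fell in 7 (adjusted p = 0.175), with Ankrd1 higher (6.33 ± 0.23) and Cyr61, a matricellular gene, lower (-1.19 ± 0.11).

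All 26 cell cycle genes rose in 2D-2D over sorted cells (adjusted p = 6.24e-10, and adjusted p = 0.154 with an estimated correlation), Plk1 by 5.14 ± 0.12. Hypoxia and glycolysis genes rose in 18 of 24 (adjusted p = 3.62e-06, and adjusted p = 0.316 with an estimated correlation), with the glycolytic enolase Eno1 at 4.31 ± 0.16. Immediate early and heat shock genes fell in 22 of 23 (adjusted p = 3.01e-07, and adjusted p = 0.131 with an estimated correlation), with Fosb at -10.17 ± 0.70 and Fos at -6.56 ± 0.30. The mean log2 CPM of this list was 10.014 to 10.124 in sorted libraries and 5.82 to 6.597 in the cultured ones, on either substrate. No library shows the cells before isolation. A rise during isolation and a fall in culture therefore cannot be told apart, here or for 3D-3D. The metalloproteases Mmp10 (9.38 ± 0.21) and Mmp13 (7.07 ± 0.20) and the inhibitor Timp1 (4.86 ± 0.11) rose. Their list of proteases and inhibitors was not called, with 12 higher and 9 to 11 lower when 1 library was left out. The acute phase protein Saa3 (9.36 ± 0.23), the neutrophil chemokine Cxcl5 (7.31 ± 0.31) and Asns, asparagine synthetase (5.24 ± 0.14), rose as well. Il1b (-7.29 ± 0.18) and Cxcl15 (-7.55 ± 0.51) fell. Endothelial (18 of 18), lymphocyte (14 of 14) and red blood cell markers (5 of 5) fell, at adjusted p = 0.0155, 0.00199 and 0.0673 with an estimated correlation and at 5.16e-08, 1.28e-06 and 0.00109 with the preset one. Ace (-8.82 ± 0.17), Cd79a (-10.88 ± 0.31) and Scgb1a1, the club cell secretory protein (-9.78 ± 0.38), fell with them. C1qb, a complement gene of macrophages (4.58 ± 0.09), and Lyz2 (0.53 ± 0.12, adjusted p = 0.000221, or 0.20 and 0.091 scaled by library size alone) rose, although the macrophage list was not called (9 higher, 13 lower of 22, adjusted p = 0.737). Airway markers fell in 15 of 16 (adjusted p = 9.75e-05, and adjusted p = 0.117 with an estimated correlation), and cholesterol synthesis genes rose in 14 of 22 and fell in 1 (adjusted p = 0.00526, and adjusted p = 0.273 with an estimated correlation). Mesothelial markers fell in 10 of 12 and rose in 1 (adjusted p = 0.0287, and adjusted p = 0.154 with an estimated correlation). In all, 12456 of 14715 genes differed (5669 higher, 6787 lower), 7674 by at least 2-fold. Genes at 0 in sorted cells included the peptide hormone Cck (at least 6360-fold higher), Hsd3b6 (1400-fold) and Gzme (647-fold). Genes at 0 in 2D-2D included the complement component C7 (at least 9660-fold lower), the lymphoid chemokine Ccl21a (7140-fold), Clec3b (5560-fold) and the scavenger receptor Scara5 (2740-fold). Scaled by library size alone, the median moved by -0.325 and 4442 genes were higher and 8026 lower.

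In 3D-3D against sorted cells the alveolar fibroblast markers also fell in 17 of 17 cases (adjusted p = 4.6e-08, and adjusted p = 0.0206 with an estimated correlation) and the adventitial ones in 15 of 17 with 1 higher (adjusted p = 5.04e-05, and adjusted p = 0.0235 with an estimated correlation). Inmt (-9.92 ± 0.21), Mfap4 (-4.17 ± 0.19) and Pdgfra (-0.38 ± 0.10) were lower, and Dcn was at 0.01 ± 0.09 (adjusted p = 0.907). Contractile genes rose in 10 of 16 and fell in 4 without a list call (adjusted p = 0.0817): Actg2 (2.60 ± 0.24), Cnn1 (2.52 ± 0.27) and Acta2 (2.47 ± 0.17) rose. Basement membrane genes fell in 13 of 14 and rose in 1 (adjusted p = 0.000129, and adjusted p = 0.23 with an estimated correlation), and of the structural genes Tnc rose (2.88 ± 0.12) and Col14a1 fell (-4.00 ± 0.11). Among YAP and TAZ targets, which were not called as a list (adjusted p = 0.0667), Nt5e, the ecto-enzyme CD73 (3.54 ± 0.12), and Ankrd1 (2.36 ± 0.26) rose and Cyr61 (-3.80 ± 0.12) and Ctgf (-1.30 ± 0.11) fell. Proteases and inhibitors rose in 17 of 24 and fell in 7 (adjusted p = 0.0128, and adjusted p = 0.181 with an estimated correlation), with Mmp10 (8.52 ± 0.22) and Mmp13 (7.98 ± 0.20). Cell cycle genes rose in 25 of 26 (adjusted p = 4.14e-08, and adjusted p = 0.23 with an estimated correlation, with Cdk1 at 3.25 ± 0.18). Hypoxia genes rose in 23 of 24 with 1 lower (adjusted p = 4.14e-08, and adjusted p = 0.304 with an estimated correlation, with Egln3 at 5.32 ± 0.39). Cholesterol synthesis genes rose in 17 of 22 with 3 lower (adjusted p = 0.000714, and adjusted p = 0.23 with an estimated correlation). Immediate early and heat shock genes fell in 21 of 23 (adjusted p = 1.62e-08, and adjusted p = 0.125 with an estimated correlation), Hspa1a, which shares sequence with a neighbouring copy and is uncertain (-7.63 ± 0.19), and Fosb (-7.33 ± 0.60) among them, while Fosl1 rose (2.04 ± 0.14).

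Saa3 (11.56 ± 0.24) and Cxcl5 (9.83 ± 0.28) were higher in 3D-3D than in sorted cells. Endothelial markers fell in 18 of 18 (adjusted p = 1.62e-08, and adjusted p = 0.0119 with an estimated correlation, with Ace at -3.31 ± 0.12). Lymphocyte markers fell in 14 of 14 (adjusted p = 5.12e-07, and adjusted p = 0.00153 with an estimated correlation, with Cd79a at -3.43 ± 0.17), and mast cell and basophil markers in 7 of 8 with 1 higher (adjusted p = 0.00494, and adjusted p = 0.0415 with an estimated correlation). Red blood cell markers fell in 5 of 5 (adjusted p = 9.51e-05, and adjusted p = 0.0235 with an estimated correlation). Airway markers were not called as a list (adjusted p = 0.186), with 7 higher and 9 lower of 16, Scgb1a1 falling (-11.88 ± 0.44); C1qb (5.03 ± 0.09) and Lyz2 (1.03 ± 0.12) rose. Cck was at least 1300-fold and Krt17 at least 590-fold higher than in sorted cells, where both were at 0. The hemoglobin genes Hba-a1 and Hba-a2 were at 0 in 3D-3D and at least 3490-fold and 2290-fold lower, values that are uncertain because the copies are nearly identical. Ccl21a stood at 0.0233 ± 0.0467 CPM in 3D-3D, where 1 library held its counts, and at 307 ± 24.8 CPM in sorted cells. In all, 11451 genes differed (5668 higher, 5783 lower), 5587 by at least 2-fold. Adjusted over the list alone, the counts of the lists given for 2D-2D and 3D-3D against sorted cells were the same, except that 18 cholesterol synthesis genes instead of 17 were higher in 3D-3D, and 13 of them instead of 14 higher and 2 cytoskeletal genes instead of 1 lower in 2D-2D.

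The moved cultures differed from sorted cells in 11497 genes for 2D-3D (5620 higher, 5877 lower; 5685 by at least 2-fold) and 12346 for 3D-2D (5606 higher, 6740 lower; 7470 by at least 2-fold). With library size alone as the scaling, 5298 were higher and 6067 lower in 2D-3D and 4662 higher and 7678 lower in 3D-2D. In 2D-3D, Saa3 (10.34 ± 0.23), the arginine-degrading Arg1 (10.05 ± 0.29), Cnn1 (3.52 ± 0.26) and Acta2 (2.87 ± 0.18) rose and Inmt (-11.12 ± 0.23), Cyr61 (-4.38 ± 0.12) and Mfap4 (-3.43 ± 0.19) fell. In 3D-2D, Cnn1 (8.35 ± 0.25), Actg2 (7.54 ± 0.24) and Acta2 (6.74 ± 0.21) rose and Inmt (-11.99 ± 0.24), Mfap4 (-7.92 ± 0.23) and Cyr61 (-1.21 ± 0.11) fell. Cck was at least 1590-fold higher in 2D-3D and 5640-fold in 3D-2D, and in 3D-2D Gzme (749-fold) and Mcpt8 (677-fold) also rose from 0. Ccl21a was at least 8690-fold and 7600-fold lower, Sec14l3 at least 3840-fold lower in 2D-3D and the carboxylesterase Ces1d at least 6230-fold lower in 3D-2D.

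As a summary over all genes, the root mean square log2 distance from the sorted mean was smallest for 3D-3D (1.797 ± 0.016, SD, n = 4), followed by 2D-3D (1.96 ± 0.04), 3D-2D (2.14 ± 0.014) and 2D-2D (2.246 ± 0.022). The difference between 3D-3D and 2D-2D was -0.449, with all 4 libraries of 3D-3D nearer than those of 2D-2D (two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 allows). Each neighbouring pair in that order differed with the same exact p of 0.0286. Measured as 1 minus Spearman's correlation, 3D-3D and 2D-3D were at 0.179 ± 0.006 and 0.183 ± 0.006 (exact p = 0.4857) and 2D-2D and 3D-2D at p = 0.0571.

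**Figure D4:**
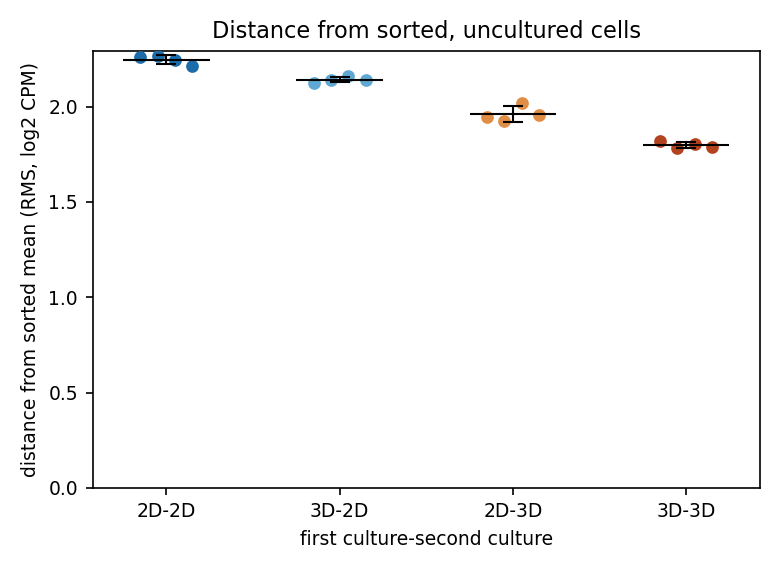
Root mean square log2 distance of each cultured library (point) from the mean of the sorted libraries, with group mean and SD (n = 4). The 3D-3D libraries centre on 1.797 and the 2D-2D libraries on 2.246.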

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

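All tests of explanations and of other splits in this part were written after the results they concern had been seen.

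Contractile genes were lower in 3D-3D than in 2D-2D (16 of 16). The scaling is argued against by 16 of 16 being called lower with RLE factors and with library size alone, and a lone library by 16 of 16 called without any 1 library. A lower share of fibroblasts stays open: the 32 alveolar and adventitial fibroblast markers went both ways (19 higher, 12 lower, median 1.24, quartiles -1 and 4). Their median lay 3.94 above the contractile median of -2.69, less than the distance of 5 between their quartiles. The alveolar markers held 0.0463% of counts in 2D-2D and 0.0961% in 3D-3D, and the adventitial markers 0.175% and 0.406%. Both shares were thus higher in 3D-3D, the opposite of a lower share of fibroblasts. They lay below the 1.35% and 0.78% of sorted cells, so these markers follow fibroblasts in culture poorly. A different share of smooth muscle cells and a biological response to the second substrate also stay open and were not tested.

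Of 15 keratin genes, 13 were higher in 3D-3D than in 2D-3D and 0 lower. A lone library is argued against, since without any 1 library 13 of the 13 called genes were still called. Epithelial cells that lived on through the first culture in 3D could account for it, and 5 of 7 airway markers other than keratins were also higher. That count is weak, since a marker near 0 in the other cultures passes the filter only through 3D-3D. RNA of the digest carried over in the proportions left in the sorted cells would move keratins and other epithelial markers alike. From sorted cells to 3D-3D the lower quartile of the 15 keratin genes (2.02) lay 3.7 above the upper quartile (-1.68) of 20 airway and alveolar type 2 markers other than keratins with at least 10 CPM in sorted cells (medians 2.88 and -3.57). The markers were chosen by their level in sorted cells, and the keratin genes without that filter after they were seen high in 3D-3D. This choice by itself widens the gap. Yet Krt7 (26.4 to 194 CPM), Krt8 (19 to 107 CPM) and Krt18 (12.6 to 70 CPM) met the same filter in sorted cells and rose. Krt19 varied too widely to tell (114 to 160 ± 83.3 CPM). Krt17 and Krt6a had 0 counts in sorted cells and 2685 and 1915 in 3D-3D. Together these values argue against carry-over in these proportions for the keratins. Carry-over in other proportions stays open, since the digest was not measured and the sorted cells had been depleted of EpCAM cells. Expression of keratins by fibroblasts was not tested and stays open.

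Interferon response genes were lower in 3D-2D than in 2D-2D (15 of 18). A lower share of macrophages is argued against by the macrophage markers, with a median change of 0.71 (20 of 22 higher, 1 lower). Under both other scalings at least 15 were called lower, and without any 1 library at least 15. A response of the cells to the first substrate stays open and was not tested.

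With libraries regrouped in all 35 ways of 4 against 4, only the real split gave as many genes called in each comparison of groups. The numbers were 10078 for 3D-3D against 2D-2D, 9763 for 2D-3D against 2D-2D, 2793 for 3D-2D against 2D-2D and 12456, 11451, 11497 and 12346 for 2D-2D, 3D-3D, 2D-3D and 3D-2D against sorted (highest other 0 in each). They were 9662 for 3D-2D against 3D-3D (highest other 593) and 3793 for 2D-3D against 3D-3D (highest other 202). The other splits mix groups that differ, which adds to the spread within them and lowers their counts. The real split is 1 of 35, the smallest share possible, and this does not exclude chance. For the number of lists, only the real split gave as many in 2D-3D against 3D-3D (20, highest other 17, 1 split of 35). Other splits gave as many, counted here with the real one, in 3D-3D against 2D-2D (16, highest other 17, 5 splits), 2D-3D against 2D-2D (9, 12, 11 splits), 3D-2D against 3D-3D (12, 20, 7 splits), 3D-2D against 2D-2D (14, 15, 3 splits), 2D-2D against sorted (19, 20, 7 splits) and 3D-3D against sorted (15, 17, 9 splits). In a set of 100 groupings, the real one and random draws of the 16 culture labels, 4 gave at least the real count of 2654 interaction genes (highest other 7327, whose source was not tested). As high a correlation came from 4 for second-culture effects (0.772, highest other 0.804) and from 11 for first-culture effects (0.572, highest other 0.842). The draws mix groups that differ in many genes, so substrate effects enter the drawn contrasts. They are therefore no measure of chance for an interaction or for these correlations, and chance was not excluded.

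Single libraries far from the others of their group were found by Dixon's ratio for 24 of 362 gene and group pairs (18.1 expected, since chance flags about 1 in 20) and 3 of 28 measures of libraries (1.4 expected). In 2D-2D these were Agt (0.858, replicate 2 library), Chl1 (0.988, replicate 3), Cxcl5 (0.93, replicate 4), Krt17 (0.956, replicate 1, low), Krt7 (0.991, replicate 2) and Npnt (0.859, replicate 4). In 2D-3D they were Ltf (1, replicate 1), Saa3 (0.844, replicate 3) and the share of macrophage markers (0.884, replicate 1, low). In 3D-2D they were Aqp4 (1, replicate 1), Sprr2a1 and Sprr2a2 (0.989 each, replicate 2), Zyx (0.925, replicate 1, low), the position (0.907, replicate 1, high) and the total counts (0.955, replicate 1, low). In 3D-3D they were Ccl21a (1, replicate 1), Egln3 (0.912, replicate 3), Fosl1 (0.98, replicate 3), Hsd3b6 (1, replicate 4), Krt6a (0.86, replicate 1), Postn (0.883, replicate 3, low) and Tead1 (0.832, replicate 2). In sorted cells they were Acta2 (0.85, replicate 2, low), Dcn (0.94, replicate 3), Egln3 (0.917, replicate 3, low), Nt5e (0.846, replicate 3, low) and Sec14l3 (0.924, replicate 2, low).

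Effects of the second substrate differed by the first culture for the following named genes, as the effect after 3D less that after 2D on the log2 scale. Higher after 3D were Krt20 (9.44), Sprr2a1 and Sprr2a2 (6.24), Sprr2b (5.66), Krt19 (5.53), Acta1 (2.87), Tead4 (2.35), Gzme (2.2), Igfbp3 (2.08), Ankrd1 (1.25), Eln (1.04), Npnt (0.84), Dcn (0.78), Timp1 (0.78), Csf1 (0.66), Ctgf (0.46) and Yap1 (0.38). Lower after 3D were Ccl8 (-3.97), Cx3cr1 (-3.36), Wisp2 (-2.94), Ace (-1.65), Mmp2 (-1.46), Lyz2 (-1.37), Ctsk (-1.2), Postn (-1.03), Col11a1 (-0.97), Nid2 (-0.78), Mmp13 (-0.59) and Tgfb1 (-0.48). Cldn2 (adjusted p = 0.0491) and Hsd3b1 (adjusted p = 0.0252) had 0 counts in a group and are given without a fold.

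Lists called with an interaction above 0 were cholesterol synthesis (19 of 22 above, 1 below, adjusted p = 1.44e-09), hypoxia (12 of 24, 4.09e-05), collagen crosslinking (10 of 15, 0.000104), airway markers (3 of 10, 0.000188), immediate early genes (13 of 23, 1 below, 0.000741), integrins (10 of 18, 1 below, 0.000865), endothelial markers (8 of 18, 1 below, 0.000865), peribronchial markers (5 of 9, 0.00228), collagens (11 of 26, 2 below, 0.00732), TGF-beta response (10 of 17, 1 below, 0.00732), cytokines (11 of 32, 3 below, 0.00843), YAP and TAZ targets (7 of 22, 0.017), lymphocyte markers (1 of 7 above and 1 below, median 1.85, 0.0221), cell cycle (2 of 26, 0.0266) and basement membrane genes (5 of 12, 1 below, 0.0472). Macrophage markers were below 0 (19 of 22, 1 above, 1.48e-16). None was called with an estimated correlation, where the lowest adjusted p was 0.135. The cell cycle genes above 0 ran from 0 to 10 with 1 library left out, 10 without 3D-3D replicate 3, and were 0 scaled by library size alone. The hypoxia genes above 0 ran from 8 to 16. Above 0 were 8 immediate early genes without 3D-3D replicate 1 or 3D-3D replicate 2, 3 basement membrane genes without 3D-2D replicate 1 and 5 airway markers without 3D-3D replicate 4. Lymphocyte markers above 0 were 0 without 2D-2D replicate 2, and 2 without 2D-3D replicate 3 or 3D-3D replicate 2.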

How the results depend on the processing

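All alternatives were fixed before the data were examined, except the scaling by library size alone, which was chosen after seeing the data. With a change of at least 2-fold required as well, the genes called numbered 3944 for 3D-3D against 2D-2D, 3799 for 2D-3D against 2D-2D, 3357 for 3D-2D against 3D-3D, 1179 for 2D-3D against 3D-3D, 653 for 3D-2D against 2D-2D, 873 for the interaction, and 7674, 5587, 5685 and 7470 for 2D-2D, 3D-3D, 2D-3D and 3D-2D against sorted, by the stricter threshold. With an estimated correlation, lists called fell to 3 of 16 for 3D-3D against 2D-2D, 0 of 9 for 2D-3D against 2D-2D, 0 of 12 for 3D-2D against 3D-3D, 6 of 20 for 2D-3D against 3D-3D, 2 of 14 for 3D-2D against 2D-2D, 3 of 19 for 2D-2D against sorted and 6 of 15 for 3D-3D against sorted. Over genes with at least 10 CPM, Pearson's correlations of second-culture and first-culture effects were 0.88 and 0.453, and Spearman's 0.874 and 0.113. The cause of this change was not tested. Without 1 library, the position of 2D-3D ran from 0.788 to 0.797 and that of 3D-2D from 0.17 to 0.198 (exact p = 0.0571, the smallest possible), the first-culture correlation from 0.521 to 0.562, and the distance of 3D-3D less that of 2D-2D from -0.46 to -0.443. Over the 1388 pairs of gene and comparison of the naming rule, 10357 of 10432 values under other settings kept direction and side of the threshold (59 weaker, 16 stronger, 0 reversed), as did 11059 of 11344 with 1 library left out (254 weaker, 31 stronger, 0 reversed) and 1336 of 1388 scaled by library size alone (38 weaker, 8 stronger, 6 reversed). The replicate numbers did not pair libraries: 24 pairs with the same number correlated by -0.096 to 0.146 (mean -0.002).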

Other observations

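Of the tests in this part, only the scaling by library size alone was chosen after the results had been seen. Some groups not described so far differed from sorted cells. In 2D-2D, markers of peribronchial and ductal myofibroblasts, which surround airways, fell in 10 of 10 cases (adjusted p = 0.00479, and adjusted p = 0.0729 with an estimated correlation), alveolar type 2 markers in 10 of 12 with 1 higher (adjusted p = 0.00715, and adjusted p = 0.154 with an estimated correlation) and neutrophil markers in 7 of 9 with 1 higher (adjusted p = 0.0361, and adjusted p = 0.316 with an estimated correlation). In 3D-3D, interferon response genes fell in 14 of 18 and rose in 2 (adjusted p = 0.0235, and adjusted p = 0.379 with an estimated correlation) and collagen crosslinking genes rose in 10 of 15 and fell in 4 (adjusted p = 0.043, and adjusted p = 0.506 with an estimated correlation).

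Cholesterol synthesis genes fell in 12 of 22 cases and rose in 3 on the move from 2D to 3D without a list call (adjusted p = 0.0535); scaled by library size alone, 8 fell and 8 rose. Interferon response genes rose in 9 of 18 and fell in 3 on that move (adjusted p = 0.408), and fell in 12 of 18 and rose in 2 on the move from 3D to 2D (adjusted p = 0.144).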
